A study of Homo sapiens with 11 samples.

How the data were processed

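Human embryonic stem cells (lines H1 and H7) were profiled by RNA sequencing in 11 libraries, 1 library per group. Of these, 9 libraries came from cells infected with a lentivirus carrying 1 of 3 short hairpin RNAs (shRNAs) and collected at day 5, and 2 libraries came from untreated H7 cells. The shRNAs were a control, uCCNE1 and pCCNE1, the last of them aimed at a primate-specific form of CCNE1, the cyclin E1 gene. Each was used in 3 cultures: primed H1, H7 held in the naive medium 5iLA and H1 held in the naive medium t2iGo. Per the labels' protocols, total RNA was taken with the RNeasy Mini kit and libraries were made with TruSeq RNA kits. Nothing in the labels puts 2 libraries in the same group.

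The deposited values were RPKM (reads scaled by transcript length in kilobases and by library size), given by the authors once per gene for 23287 genes. They sit in 2 tables, one with the 9 shRNA libraries and one with the 2 untreated libraries, which were treated as normalised separately. TopHat2 2.3.0 and Cufflinks 1.2.1, with the hg19 build, are named, with these versions, per the submitters' processing notes. The roles and settings of these tools are not given in the sources used here, nor is whether counting used strand. A gene-level RPKM sums the splice variants of a gene, so pCCNE1 and the other CCNE1 transcripts could not be separated. Short RNAs give few or no fragments in some library preparations and share reads with host genes, near-identical copies and overlapping genes, so their RPKM values were treated as uncertain. The labels describe the primed H1 libraries with a naming scheme different from that of all other libraries, which leaves open a separate preparation or run.

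Read totals are not part of an RPKM table. The depth of each library was estimated from the value of a single read, since low RPKM values fall on steps that depend on transcript length. The estimate ran from 6.41 to 25.1 M reads. A single read on a transcript of 2 kb then stood for 0.0199 to 0.0780 RPKM. Transcript length and GC content came from a GENCODE transcript file of build GRCh38. RefSeq identifiers matched 21905 genes (94.1%), 770 more were matched by symbol, and 612 had no match. No coordinate was carried between builds, so only the chromosome given by the files is printed.

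Genes with a mean RPKM of at least 1 over the libraries of their table entered the tests, 12116 genes in the shRNA table and 11015 in the untreated table. Values were analysed as log2(RPKM + 1). A fold change is on that scale throughout, and it understates the change of genes with low values. R 4.3.3 and limma 3.58.1 were used. The shRNA comparisons came from a linear model with culture and shRNA as terms over all 9 libraries, which leaves 4 residual degrees of freedom, with variance moderation along an intensity trend. The comparison of t2iGo with primed H1 used the same model. The difference of an shRNA effect between naive and primed cultures came from a model with an added term for that difference, with 2 residual degrees of freedom. Benjamini-Hochberg adjustment was applied over the genes tested, at a threshold of 0.05. A culture stands in for a replicate in these models, so genes that respond in 1 culture alone enter the residual. The p-values therefore measure only the spread between these libraries, which may be partly technical.

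A total of 26 gene lists were fixed, covering pluripotency states, lineages, cell cycle phases, signalling targets, stress, metabolism, chromatin and possible other cell types. The limma camera test with a preset correlation between genes of 0.01 was applied to the 25 lists with at least 5 tested genes. Its p-values were adjusted by the Benjamini-Hochberg method over those lists. The list of 8-cell stage genes had 1 tested member and was not tested. Camera with an estimated correlation and fry were run as alternatives. The untreated H7 pair and each shRNA library against the control of its own culture are single libraries, so no p-value was computed for them. A list's median there was placed among 10000 random lists of the same size, matched on mean expression over all libraries of the same table.

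The genes named were chosen by rule. CCNE1 and CCNE2 were always reported. For each shRNA comparison the 10 largest rises and falls past the threshold with a shared sign in the 3 cultures were taken, or the genes with the smallest p up to 5 per direction where fewer passed. For t2iGo against primed, the 10 largest rises and falls with a shared sign for the 3 shRNAs were taken. For untreated H7 these were the 10 largest differences per direction among genes of at least 5 RPKM in the higher library, and within each culture the 3 largest. For the naive minus primed differences, the 3 smallest p per direction were taken, and up to 4 members of each list in each comparison. A gene that this rule names for uCCNE1 against control is not reported here. Of the genes it names for single cultures and for the H7 pair only some are given. Any further gene named was picked after its values were seen, mostly protein-coding genes of a single culture or of the H7 pair, where short RNAs filled most of the places. The grouping, the tests, the lists, the naming rule and the first group of alternatives below were set before the data were examined.

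The alternatives of the first group were a pseudocount of 0.1, no filter, quantile normalization, median-ratio scaling, no variance trend, no blocking term (for the shRNA comparisons, no culture term), a fit on the 6 libraries compared, and leaving out each culture or shRNA in turn. Restricting the tests to protein-coding RefSeq entries, removing a loess trend on GC content and length (span 0.3), testing the lists on the naive minus primed difference, leaving out 1 naive library in turn or the other shRNA from that difference (1 residual degree of freedom), and applying an estimated correlation under both other scalings to t2iGo against primed were added after seeing the data. The correlation between the pCCNE1 and uCCNE1 effects was set beside 100 simulations of unchanged groups that shared the same controls, and so was, after seeing the data, the share of genes below control in all 6 libraries with a CCNE1 shRNA. In a check for mixed-up samples, 0 of 11 libraries mismatched their labelled cell line.

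The fits were tested on simulated data drawn for 12116 genes, with 100 genes changed per fold size among those with a mean log2 value above 2. All of them were changed together, by the same size in each library of the changed group, with noise independent between genes. Many true changes ease the adjusted threshold. The recovery below therefore may overstate that in a comparison where few or no genes change, and a count of 0 does not show that changes of these sizes are absent. For t2iGo against primed the simulated data held no other culture effect. A log2 change of 1 was recovered in 76% of changed genes for pCCNE1 against control, 78% for uCCNE1 against control, 82% for pCCNE1 against uCCNE1 and 81% for t2iGo against primed. A log2 change of 2 was recovered in 100% of changed genes in each of these 4 comparisons. For the naive minus primed difference the recovery was 0% at a log2 change of 1, and 46% (pCCNE1) and 62% (uCCNE1) at a log2 change of 2. Among unchanged genes, 11, 17, 19 and 12 were called in the first 4 comparisons, in that order, and 7 (pCCNE1) and 19 (uCCNE1) in the naive minus primed difference.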

Results

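RNA was sequenced from human embryonic stem cells of the lines H1 and H7, held as primed cells or in 1 of 2 media for the earlier, naive state of pluripotency (5iLA and t2iGo). In 9 libraries the cells carried a control shRNA, an shRNA named uCCNE1 or an shRNA against pCCNE1, a primate-specific splice form of the cyclin E1 gene CCNE1, and were collected 5 days after lentiviral infection. These cover primed H1, 5iLA naive H7 and t2iGo naive H1, with 1 library per shRNA and culture. The other 2 libraries were untreated primed H7 and untreated 5iLA naive H7. There were no replicates within a group, so tests used the 3 cultures, or the 3 shRNAs, in their place. The estimated depth was 18.9 to 24.0 M reads in primed H1, 11.5 to 16.8 in 5iLA H7 and 6.41 to 14.1 in t2iGo H1, and 13.6 and 25.1 in untreated primed and 5iLA H7.

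The primed H1 libraries stood apart from all others in their short RNAs. Small non-coding RNAs held 0.218% to 0.521% of summed RPKM in primed H1, against 16.1% to 27.5% in 5iLA H7 and 13.1% to 16.7% in t2iGo H1. In the untreated table, which was treated as normalised separately, their share was 9.85% in primed H7 and 31.6% in 5iLA H7. Histone genes held 0.00581% to 0.0114% in primed H1, 0.283% to 0.621% in 5iLA H7, 0.297% to 0.640% in t2iGo H1 and 1.11% in untreated primed H7. The summed RPKM was 341088 to 357685 in primed H1 and 139202 to 224314 in the other 6 shRNA libraries.

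The target gene CCNE1 (NM_001238, chromosome 19), whose product drives entry into S phase with CDK2, was lower than in the matched control in all 6 libraries with a CCNE1 shRNA. In primed H1 its level was 11.95 RPKM with the control shRNA, 6.75 with uCCNE1 and 10.5 with pCCNE1, so 56.4% and 88.2% of control. In 5iLA H7 it was 14.1, 5.27 and 8.38 RPKM in the same order (37.3% and 59.3%), and in t2iGo H1 it was 9.65, 5.38 and 5.25 RPKM (55.8% and 54.4%). Untreated H7 cells held 5.65 RPKM when primed and 8.48 RPKM in 5iLA. Averaged over the 3 cultures, the log2 difference from control was -0.92 ± 0.20 (SE) for uCCNE1 and -0.54 ± 0.20 for pCCNE1, with limma p-values of 6.23e-04 and 0.0182. Neither passed Benjamini-Hochberg adjustment over 12116 genes (limma, adjusted p = 0.349 and 0.246). The value for a gene sums its splice forms, so the level of pCCNE1 itself was not measured. CCNE2 (NM_057749, chromosome 8), the other cyclin E gene, was at 0.34 ± 0.20 for uCCNE1 and 0.19 ± 0.20 for pCCNE1 (limma, adjusted p = 0.580 and 0.692).

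**Figure D1:**
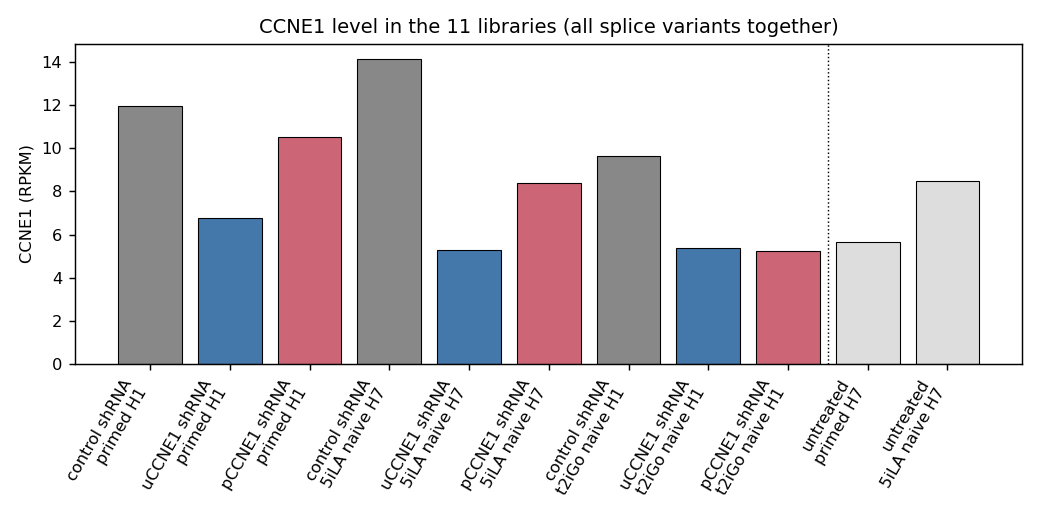
Bars show the RPKM of CCNE1 in each of the 11 libraries, 1 library per bar, with no error bars because no group has a replicate. The control libraries sit at 9.65 to 14.1 RPKM and the uCCNE1 libraries at 5.27 to 6.75 RPKM. The untreated libraries come from a table treated as normalised separately.

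The first comparison asked which genes respond to loss of pCCNE1 across primed and naive cultures. The genes with the smallest p did not pass the threshold and had values below control in all 3 cultures. CYBA, a subunit of the NADPH oxidase, was at a log2 difference of -1.43 ± 0.18, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, at -1.41 ± 0.19 and GUK1, a guanylate kinase, at -1.48 ± 0.21 (limma, adjusted p = 0.0617 each). PCK2 went from 84.3 RPKM with the control shRNA to 32.1 in primed H1, from 6.78 to 1.70 in 5iLA H7 and from 5.04 to 1.41 in t2iGo H1. RPS28 was at -1.41 ± 0.21 and MPG at -1.11 ± 0.19 (limma, adjusted p = 0.0794 and 0.196). Among genes with higher values, the smallest p belonged to SEPP1 at 0.87 ± 0.18, NBPF16 at 0.78 ± 0.17, ALCAM at 1.08 ± 0.24, SGK1 at 0.74 ± 0.17 and HDAC9 at 0.73 ± 0.18 (limma, adjusted p = 0.200 each). NBPF16 and RPS28 have near-identical copies, so their values are uncertain.

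By limma, 0 of 12116 genes passed for pCCNE1 against control, while 1792 had an unadjusted p under 0.05 where 606 would be met by chance. The median gene lay at -0.15, beside a median SE of 0.198, and 33.6% of genes had the same sign in all 3 cultures. A shift or GC trend of a whole library also gives small p-values over many genes. The excess over 606 therefore does not count genes that respond to the shRNA. Without the t2iGo libraries 94 genes passed (21 higher, 73 lower), and without the primed libraries 6 passed (1 higher, 5 lower). Restricted to protein-coding entries, an alternative chosen after seeing the data, 4 passed, all lower: CYBA, PCK2 and GUK1 (limma, adjusted p = 0.0105) and RPS28 (0.0129).

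Of the 25 gene lists tested, 6 differed from the other genes after pCCNE1 shRNA, and none did with an estimated correlation. The list of integrated stress and unfolded protein response genes was lower, with a median of -0.41 and 20 of 23 members below 0 (limma camera, adjusted p = 0.00347, and adjusted p = 0.951 with an estimated correlation). Over all genes 0 of its members rose or fell and 23 did not pass, while 8 fell when adjusted over the list alone. Its members include PCK2, the glutathione-degrading enzyme CHAC1 at -1.20 ± 0.26, SHMT2 at -0.70 ± 0.20 and TRIB3 at -0.63 ± 0.19 (limma, adjusted p = 0.200, 0.203 and 0.203). The call was lost without the culture term, without the primed libraries and without the 5iLA libraries. Fibroblast and feeder genes were higher as a set, with a median of 0.18 and 9 of 14 members above 0 (limma camera, adjusted p = 8.83e-04, and adjusted p = 0.951 with an estimated correlation). Over all genes 0 of them passed, and 1 (COL3A1) rose when adjusted over the list alone. COL3A1 was at 1.12 ± 0.29 and LUM at 1.01 ± 0.31 (limma, adjusted p = 0.200 and 0.203), and LUM stood at 13.9 RPKM with control and 71.5 RPKM with pCCNE1 shRNA in t2iGo H1. That call ended under quantile normalization, under median-ratio scaling and without the 5iLA libraries.

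The other 4 lists called for pCCNE1 were higher relative to the remaining genes, with 0 members passing over all genes and 0 when adjusted over the list alone. Endoderm genes had a median of 0.18 with 7 of 11 above 0, and trophoblast genes a median of 0.37 with 4 of 6 above 0 (limma camera, adjusted p = 0.0304 and 0.0338, and adjusted p = 0.951 with an estimated correlation). Primed pluripotency genes had a median of 0.04 with 14 of 24 above 0, and targets of ERK signalling a median of -0.01 beside a mean of 0.01 and an upward test (limma camera, adjusted p = 0.0360 each, and adjusted p = 0.951 with an estimated correlation). None of these 4 calls held with a pseudocount of 0.1, under quantile normalization, under median-ratio scaling, without the culture term or without the 5iLA libraries, where the trophoblast median turned to -0.05. The endoderm call was also lost without a filter and without the t2iGo libraries, and the primed and ERK calls without a filter and without the primed libraries. Cofactors of enhancers and the Mediator complex, which the study's title makes of interest, had a median of -0.15, equal to that of all genes to 2 decimals (limma camera, adjusted p = 0.744). The list of 8-cell stage genes had 1 tested member of 21.

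After uCCNE1 shRNA, the smallest p belonged to MUTED, a subunit of a lysosome-related organelle complex, at -1.88 ± 0.25 (limma, adjusted p = 0.104). Its RPKM was 2.21 in primed H1 against 8.74 in control, and it was listed at 0 in both naive uCCNE1 libraries. The read-through gene EEF1E1-MUTED, which overlaps it, was at 1.54 ± 0.33 (limma, adjusted p = 0.349), so both values are uncertain. NUDT14 was at -1.06 ± 0.17 and PCK2 at -1.10 ± 0.19 (limma, adjusted p = 0.211 and 0.222), and SNORA3 was listed at 0 in all 3 uCCNE1 libraries. Among higher genes, TAGLN, an actin-binding protein of smooth muscle, was at 1.11 ± 0.27, ABCG2 at 0.86 ± 0.21, ITM2A at 0.95 ± 0.23 and ANXA1 at 1.37 ± 0.35 (limma, adjusted p = 0.349 each). ANXA1 went from 3.85 to 24.4 RPKM in 5iLA H7 and from 20.7 to 51.5 RPKM in t2iGo H1.

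By limma, 0 of 12116 genes passed for uCCNE1 against control and 1236 had an unadjusted p under 0.05. The median gene lay at -0.14, so that count has the same limit as the one for pCCNE1. Without the t2iGo libraries 123 genes passed (24 higher, 99 lower), without the primed libraries 4 did, all lower (SNORA6, SNORA28, SNORA45 and SCARNA21, named after their values were seen), and a fit on the 6 libraries compared gave 38 (5 higher, 33 lower). Among those 123, named after their values were seen, were the interferon-induced genes BST2 at -2.03 and ISG15 at -1.33, and the stress gene DDIT4 at -1.87.

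The stress and unfolded protein response list was again lower, with a median of -0.57 and 22 of 23 members below 0 (limma camera, adjusted p = 3.93e-08, and adjusted p = 0.892 with an estimated correlation). Over all genes 0 members passed, and 11 fell when adjusted over the list alone. DDIT4, an inhibitor of mTORC1, was at -1.35 ± 0.29, TRIB3 at -0.88 ± 0.19 and NUPR1 at -0.86 ± 0.22 (limma, adjusted p = 0.349 each). Replication-dependent histones had a median of -0.65 with 15 of 15 below 0, and 0 passed over all genes or when adjusted over the list alone (limma camera, adjusted p = 0.00158, and adjusted p = 0.966 with an estimated correlation). That call was lost without the t2iGo libraries and without the culture term, and the histone median was 0.16 in primed H1, where these RNAs were scarce. Genes of G2 and mitosis had a median of -0.31 with 24 of 24 below 0 on average over the cultures and 0 passing either way (limma camera, adjusted p = 0.0218, and adjusted p = 0.966 with an estimated correlation). By culture their median was -0.14 in primed H1, -0.79 in 5iLA H7 and 0.00375 in t2iGo H1, where 12 were above 0 and 12 below. That call was lost with a pseudocount of 0.1, under median-ratio scaling and without the 5iLA libraries. Primed pluripotency genes were called upward with a median of -0.01 and a mean of 0.06, and trophoblast genes with a median of 0.19 (limma camera, adjusted p = 0.00491 and 0.0218, and adjusted p = 0.892 with an estimated correlation). Of these lists 11 of 24 and 5 of 6 members were above 0, and 0 passed over all genes or when adjusted over the list alone. Both calls were lost under quantile normalization, under median-ratio scaling and without the 5iLA libraries, where the trophoblast median turned to -0.10. The primed call was also lost without a filter, and the trophoblast call without the culture term.

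A direct comparison of the shRNAs asked whether their effects differ. MUTED was at 1.79 ± 0.25 and EEF1E1-MUTED at -2.18 ± 0.33 in pCCNE1 against uCCNE1 (limma, adjusted p = 0.161 and 0.182), and CYBA was at -0.88 ± 0.18 and MDP1 at 1.16 ± 0.23 (limma, adjusted p = 0.845 and 0.791). FZD6, a receptor of WNT proteins, was at 1.004 ± 0.20, the metalloprotease gene ADAM9 at 1.23 ± 0.26, CGREF1 at 0.90 ± 0.19 and HIGD1A at -0.81 ± 0.18 (limma, adjusted p = 0.791 for FZD6 and 0.845 for the others). The short RNAs SNORA18 and SNORA10, with uncertain values, were at -5.28 ± 0.95 and -3.67 ± 0.81 (limma, adjusted p = 0.614 and 0.845). CCNE1 was at 0.38 ± 0.20 and CCNE2 at -0.15 ± 0.20 (limma, adjusted p = 0.990 each). By limma 0 of 12116 genes passed and 495 had an unadjusted p under 0.05. Without the t2iGo libraries 40 passed (21 higher, 19 lower). Genes of G2 and mitosis were higher with pCCNE1 than with uCCNE1, with a median of 0.25 and 21 of 24 above 0 (limma camera, adjusted p = 4.27e-06, and adjusted p = 0.850 with an estimated correlation). CENPA was at 0.69 ± 0.24, TOP2A at 0.60 ± 0.25 and CDK1 at 0.59 ± 0.27 (limma, adjusted p = 0.990 each). Cholesterol synthesis genes had a median of 0.20 and fibroblast genes of 0.25, while MYC and ribosome biogenesis genes had a median of -0.19 and DNA replication genes of -0.13 (limma camera, adjusted p = 0.00756, 0.0441, 0.00443 and 0.0441, and adjusted p = 0.850 with an estimated correlation). In these 5 lists 0 members passed over all genes, and 1 fibroblast gene, TAGLN at -1.06, fell when adjusted over the list alone. The cholesterol, MYC and DNA replication calls were lost without the primed libraries, and the DNA replication and fibroblast calls without the t2iGo libraries, with a pseudocount of 0.1 and under median-ratio scaling. The fibroblast call was also lost under quantile normalization and without the culture term.

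Across 12116 genes, which are not independent replicates, the average changes after pCCNE1 and uCCNE1 shRNA had a Pearson r of 0.582 and a covariance of 0.0515. Simulated unchanged groups against the same controls gave an r of 0.4997 and a covariance of 0.0342, a difference of 0.0173. With 1 control library per culture the controls could not be split, so part of the excess in r may come from them. Within a culture, r was 0.446 in primed H1, 0.677 in 5iLA H7 and 0.545 in t2iGo H1. Between pairs that share no control library it ran from -0.0569 to 0.229.

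**Figure D2:**
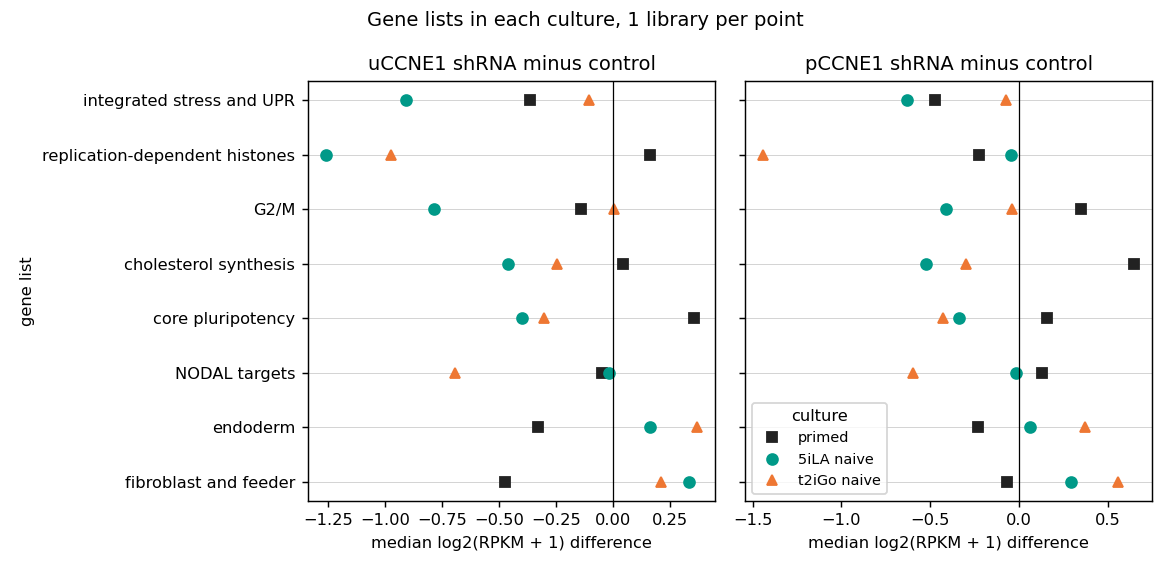
Points show the median log2(RPKM + 1) difference from control of 8 gene lists in each culture, with uCCNE1 on the left and pCCNE1 on the right and 1 library per side of each difference. The stress and unfolded protein response list (UPR) lies at -0.47 for pCCNE1 and -0.37 for uCCNE1 in primed H1, and at -0.07 and -0.11 in t2iGo H1.

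Within single cultures each difference rests on 1 library per side, so no test was made and no difference has a replicate check. In t2iGo H1 with pCCNE1 shRNA, NANOG was at 4.29 against 22.9 RPKM, POU5F1 at 13.6 against 34.6, NODAL at 5.40 against 18.98, its antagonists LEFTY1 at 0.719 against 7.17 and CER1 at 3.25 against 30.0, and GDF3 at 4.20 against 16.6. LEFTY2 went the other way, at 8.79 against 3.48 RPKM. MIXL1 stood at 5.10 RPKM in control and was listed at 0. The median of the NODAL target list was -0.60, with 12 of 14 members lower, at percentile 0 among 10000 random lists matched on expression. Core pluripotency genes were at a median of -0.43 (percentile 1.92, 12 of 15 lower), naive genes at -0.11 (percentile 49.5) and primed genes at -0.20 (percentile 19.2). Histone genes were at a median of -1.44 and ERK targets at -0.56, both at percentile 0, fibroblast genes at 0.56 (percentile 100) and endoderm genes at 0.37 (percentile 99.99). Higher than in control were AFP and TTR, which encode secreted proteins of endoderm and liver, at 21.6 against 4.71 and 9.12 against 1.85 RPKM, and SPINK1 at 14.8 against 3.08. With uCCNE1 shRNA in t2iGo H1, NANOG was at 8.21 RPKM, POU5F1 at 18.2, LEFTY1 at 1.13, CER1 at 6.03 and AFP at 18.7. The NODAL target list was at -0.70 (percentile 0) the endoderm list at 0.37 (percentile 100), the histone list at -0.97 (percentile 0) and the fibroblast list at 0.21 (percentile 99.89).

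In primed H1, some of these genes were higher than in control, while NODAL was at 1.45 against 1.47 RPKM. With pCCNE1 shRNA NANOG was at 51.2 against 18.7 RPKM, LEFTY1 at 8.54 against 1.97, LEFTY2 at 10.001 against 0.989 and the ERK target DUSP6 at 102 against 35.4, and POU5F1 was at 344 against 275. Cholesterol synthesis genes had a median of 0.65 and ERK targets of 0.44, both at percentile 100, with HMGCS1 at 353 against 142 RPKM. LHX5 was at 0.430 against 9.48 and the retinoic acid-degrading enzyme CYP26A1 at 6.01 against 41.0. With uCCNE1 shRNA in primed H1, LHX5 was at 0.287 RPKM, CYP26A1 at 3.10, DLK1 at 2.45 against 34.4, the linker histone H1F0 at 41.7 against 231 and the heat shock gene HSPA8 at 988 against 393. In 5iLA H7, ALPPL2, a marker of naive cells, was at 32.3 with pCCNE1 and 28.3 with uCCNE1 shRNA against 156 RPKM in control, and NANOG at 74.7 and 62.0 against 130. The naive list there had a median of -0.36 with pCCNE1 (percentile 13.4, 5 of 20 above 0) and -0.47 with uCCNE1 (percentile 2.53, 2 of 20 above 0), beside medians of -0.30 and -0.34 for all genes. In the same pairs, for pCCNE1 and uCCNE1 in that order, fibroblast and feeder genes were at 0.29 and 0.33 (percentile 100 each). Trophoblast genes were at 0.57 and 0.53 (percentile 99.99 each) and primed genes at 0.02 and 0.03 (percentile 100 each). The random lists were matched on the mean over all 9 shRNA libraries, not on the level in 5iLA. Primed markers such as ZIC2 and VIM were low in 5iLA, with little room to fall. Percentile 100 therefore does not show a rise of the primed list. Further lists lay high in these pairs, though not all did: endoderm genes at percentiles 97.7 and 99.8, BMP targets at 99.84 and 99.86 and WNT targets at 98.6 and 99.45. High percentiles in 5iLA were thus not particular to fibroblast and trophoblast genes, and the matching limits them too. In these 5iLA pairs GPRC5A was at 29.1 and 19.3 against 1.92, and ANXA1 at 17.9 and 24.4 against 3.85. In primed H1 the fibroblast list was at -0.07 with pCCNE1 (percentile 30.4) and -0.48 with uCCNE1 (percentile 0.12). The stress list had medians of -0.47 and -0.37 in primed H1 (percentiles 0 and 0.01) and -0.63 and -0.91 in 5iLA H7 (0.425 and 0) for pCCNE1 and uCCNE1. In t2iGo H1 they were -0.07 and -0.11 (75.4 and 2.56).

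The largest differences by the naming rule were short RNAs listed at 0 on one side, among them MIR1248 (130 RPKM with pCCNE1 shRNA, 0 in control) and PCNA-AS1 (31.4 RPKM in control, 0 with either shRNA) in primed H1, SNORD8 (227 in control, 0 with pCCNE1) in 5iLA H7 and SNORD8 (0 in control, 953 with pCCNE1) in t2iGo H1. The protein-coding genes above were named after their values were seen. For pCCNE1, 112 genes were at least 2-fold higher and 437 lower in primed H1, 106 and 594 in 5iLA H7 and 89 and 330 in t2iGo H1. For uCCNE1 the numbers were 75 and 342, 64 and 598, and 46 and 77. In 5iLA H7 the split flipped once each pair's median was removed, to 268 higher and 204 lower for pCCNE1 and 188 and 148 for uCCNE1. The change correlated across genes with GC content at r = -0.553 for pCCNE1 in primed H1 and -0.396 in t2iGo H1, against 0.0325 in 5iLA H7. For uCCNE1 it was -0.308, -0.292 and -0.0899 in the same order.

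**Figure D3:**
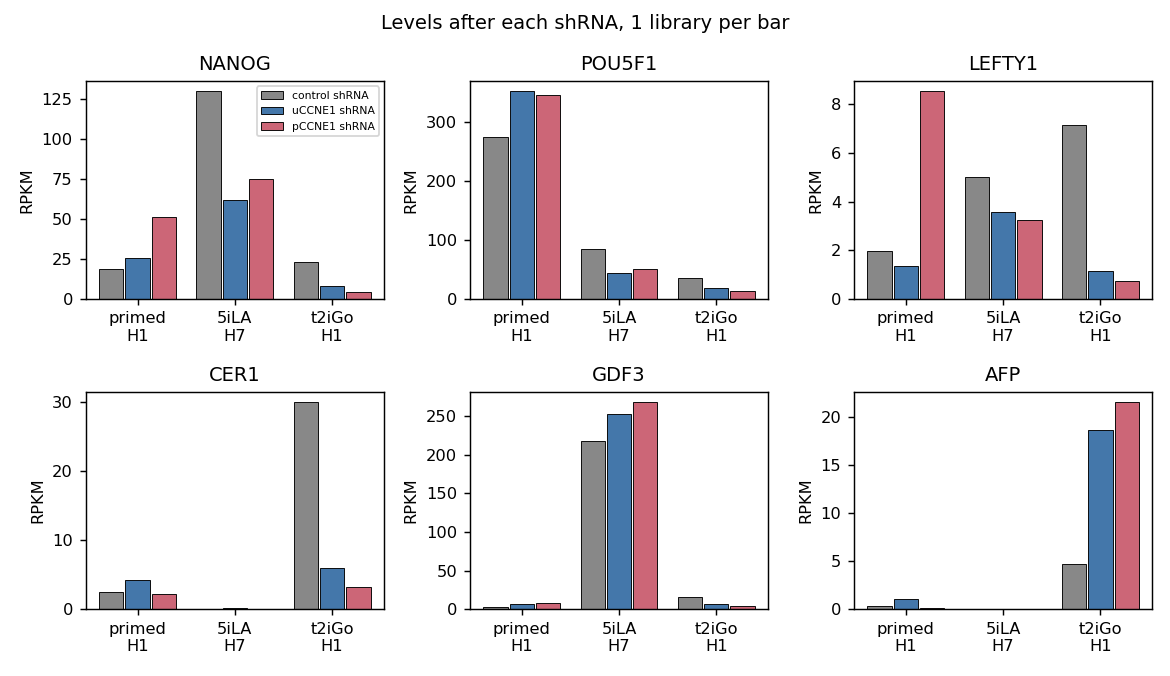
Bars show RPKM of NANOG, POU5F1, LEFTY1, CER1, GDF3 and AFP with control, uCCNE1 and pCCNE1 shRNA in each culture, 1 library per bar and no error bars. NANOG is at 22.9, 8.21 and 4.29 RPKM in t2iGo H1 and at 18.7 with control and 51.2 with pCCNE1 shRNA in primed H1.

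The comparison of t2iGo naive with primed H1 asked how the libraries of these cultures differ in the same line, with 3 libraries on each side, 1 per shRNA. The libraries labelled t2iGo held few naive markers: DPPA5 was at 0.138 RPKM in the control library against 273 in 5iLA H7, DPPA3 at 0.768 against 260, DNMT3L at 0.649 against 96.0 and KLF4 at 0.666 against 20.2. Of the primed markers, ZIC2 was at 22.0 RPKM (92.3 in primed H1, 0.0591 in 5iLA H7) and VIM at 340 (172 and 0.507), while 18 of 24 primed genes fell and the median of that list was -2.11. The largest rises were all in short structured RNAs. SCARNA7 rose by 8.65 ± 0.26 on the log2 scale, and RPPH1, the RNA of ribonuclease P, by 7.85 ± 0.30 and SNORA48 by 7.76 ± 0.30 (limma, adjusted p = 3.89e-09 for the first and 1.64e-08 for the other two). RNU11, SNORA68 and SNORA54 were listed at 0 in primed H1, and SNORA68 stood at 1733 and SNORA54 at 1480 RPKM in the t2iGo control library. Among the largest falls, MFGE8, a milk fat globule protein, changed by -6.46 ± 0.19 (740 to 7.14 RPKM), RARRES2 by -6.33 ± 0.19, GPR176 by -5.74 ± 0.18, the imprinted gene NNAT by -5.72 ± 0.27, the cytokine gene MIF by -5.40 ± 0.45 and TCF7L1, a repressor of WNT targets, by -5.11 ± 0.16 (limma, adjusted p at most 1.06e-06). The rule also named SNORA34, SNORD15B, SNORD89 and SNORD97 as rises, and PPAP2C, LECT1, WFDC2 and SNURF, which overlaps SNRPN, as falls. These directions and calls held under both other scalings. The genes given with a fall size were also lower in untreated primed H7 than in the primed H1 control. In that order, MFGE8 was at 80.7 and 740 RPKM, RARRES2 at 24.6 and 149 and GPR176 at 12.9 and 51.6. NNAT was at 1.003 and 121, MIF at 19.9 and 325 and TCF7L1 at 4.28 and 68.9. All were lower still in the t2iGo control. The untreated library is of another line and a table treated as normalised separately, so these falls cannot be put down to culture alone.

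**Figure D4:**
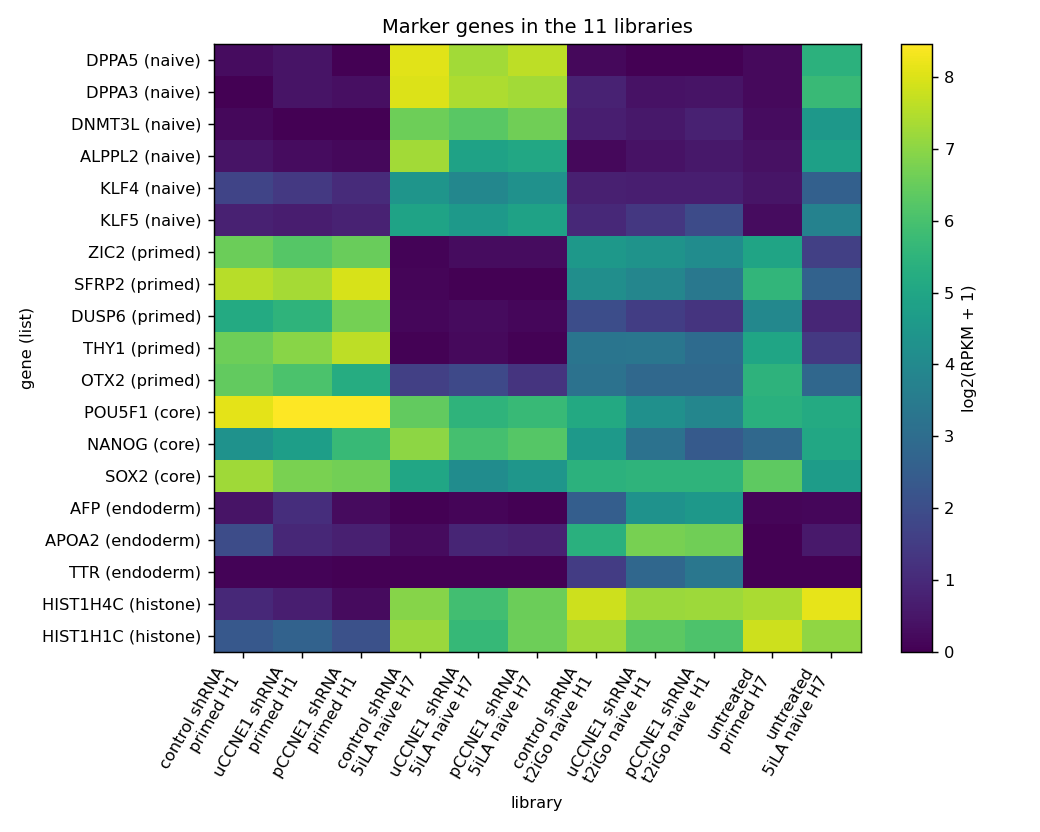
Colours show log2(RPKM + 1) of naive, primed, core, endoderm and histone genes in each of the 11 libraries, 1 column per library. The untreated libraries come from a table treated as normalised separately. DPPA5 is at 273 RPKM in the 5iLA control library and 0.138 in the t2iGo control library, and ZIC2 at 0.0591 and 22.0.

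By limma 8695 of 12116 genes changed between t2iGo and primed H1, 1062 higher and 7633 lower, and the median gene lay at -0.82. Under median-ratio scaling 3963 were higher and 4229 lower, and under quantile normalization 4145 and 4009. Directions of single genes are therefore given only where they held in all 3. Culture went together with what may be a separate preparation or run. Small non-coding RNAs held 0.218% to 0.521% of summed RPKM in primed H1 and 13.1% to 16.7% in t2iGo. The libraries of a side share 1 culture, so the p-values here and below cannot tell the culture state from such a difference. CCNE1 was at -0.48 (limma, adjusted p = 0.0438), but at 0.37 under median-ratio scaling (0.0492) and 0.34 under quantile normalization (0.0688). Leaving out any 1 shRNA ended its call, with values from -0.58 to -0.28. CCNE2 was at 0.77 ± 0.20 (limma, adjusted p = 0.00472).

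Of 25 lists, 8 were called, none with an estimated correlation. All 15 replication-dependent histones rose, also when adjusted over the list alone, with a median of 4.04 (limma camera, adjusted p = 3.36e-21, and adjusted p = 0.285 with an estimated correlation). HIST1H4C rose from 0.950 to 227 RPKM and HIST1H1E from 0.484 to 68.3. These libraries also differ in small RNA share, as given above. Of 11 endoderm genes 8 rose, 0 fell and 3 did not pass, the same when adjusted over the list alone, and the median was 1.77 (limma camera, adjusted p = 1.13e-10, and adjusted p = 0.285 with an estimated correlation). The apolipoprotein gene APOA2 rose by 5.03 ± 0.38, APOA1 by 3.08 ± 0.27 and the WNT inhibitor gene DKK1 by 2.26 ± 0.17 (limma, adjusted p at most 1.65e-06). Of 10 WNT targets 6 rose, 1 fell and 3 did not pass (7 and 1 when adjusted over the list alone), with LEF1 up by 1.94 ± 0.19. Of 7 mesendoderm and mesoderm genes 4 rose and 3 did not pass, the same when adjusted over the list alone, with HAND1 up by 2.25 ± 0.25 and PDGFRA by 1.77 ± 0.19 (limma camera, adjusted p = 6.28e-07 and 2.19e-05 for these lists, and adjusted p = 0.285 with an estimated correlation). Of 18 glycolysis and hypoxia genes 16 fell and 2 did not pass, the same when adjusted over the list alone, with a median of -1.89 (limma camera, adjusted p = 0.0267, and adjusted p = 0.586 with an estimated correlation). That call was lost with the 6 libraries compared and with the GC and length trend removed. LDHA changed by -3.12 ± 0.23 and HK2 by -2.87 ± 0.17 (limma, adjusted p = 5.74e-07 and 1.73e-07).

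Among 20 naive pluripotency genes 5 rose, 5 fell and 10 did not pass (5 and 4 when adjusted over the list alone), and the list's median was 0.16 beside a mean of -0.11 and an upward test (limma camera, adjusted p = 4.08e-04, and adjusted p = 0.384 with an estimated correlation). This call and that of the fibroblast genes (median 0.05, 6 rose and 6 fell, also when adjusted over the list alone, adjusted p = 0.00383 by limma camera and adjusted p = 0.554 with an estimated correlation) were lost under both scalings. Of 20 G1/S regulators 6 rose and 8 fell, also when adjusted over the list alone, with a median of -0.28 beside an upward test (limma camera, adjusted p = 0.00977, and adjusted p = 0.384 with an estimated correlation), while 12 rose and 2 fell under median-ratio scaling. Of 24 primed pluripotency genes 3 rose, 18 fell and 3 did not pass, and of 15 core pluripotency genes 0 rose, 11 fell and 4 did not pass, the same when adjusted over each list alone (limma camera, adjusted p = 0.142 and 0.267). Under median-ratio scaling 5 primed genes rose and 16 fell and the list was called lower (limma camera, adjusted p = 0.0234, and adjusted p = 0.738 with an estimated correlation), as under quantile normalization (0.0178, and adjusted p = 0.640 with an estimated correlation), while 3 core genes rose and 6 fell. POU5F1 changed by -3.91 ± 0.29, from 275 to 34.6 RPKM in the control libraries, and ZFP42 by -5.10 ± 0.25, with the same direction in all 3 scalings (limma, adjusted p = 5.39e-07 and 7.39e-08). NODAL rose by 2.21 ± 0.28 (limma, adjusted p = 2.34e-05). The HERVH-driven transcript ESRG fell by 3.80 ± 0.25 (limma, adjusted p = 3.01e-07).

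**Figure D5:**
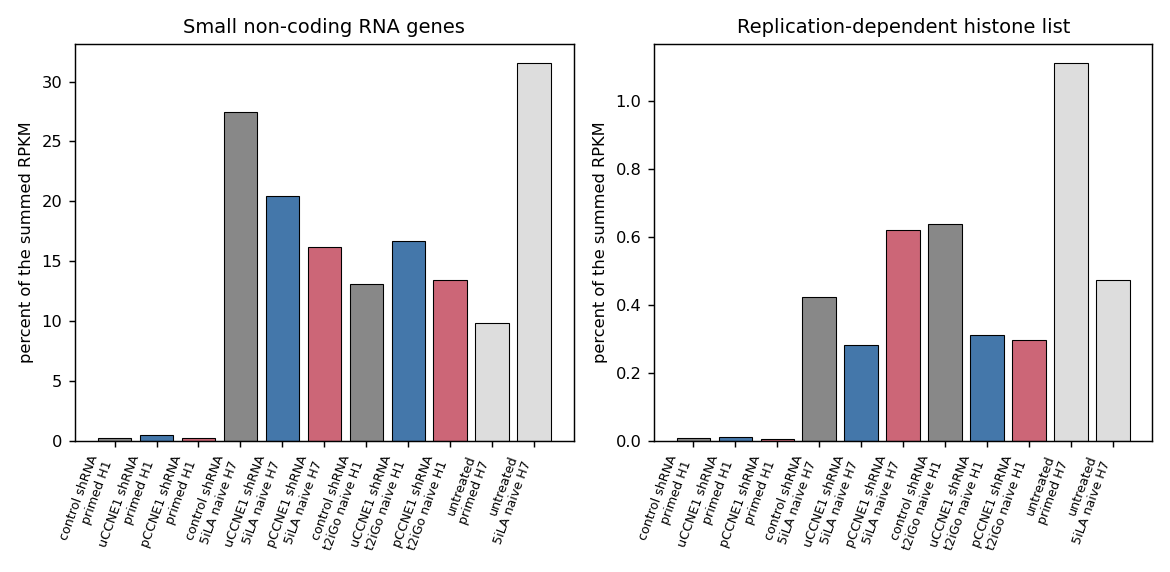
Bars show the percent of summed RPKM held by small non-coding and histone RNAs in each of the 11 libraries. The 3 primed H1 libraries hold 0.218% to 0.521% small non-coding RNA and all others at least 9.85%. The untreated libraries come from a table treated as normalised separately.

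In untreated H7, with 1 library per state and no test, naive markers were far higher in 5iLA than in primed cells. NLRP7 was at 99.4 against 0.361 RPKM, DPPA3 at 52.7 against 0.165 and DPPA5 at 42.0 against 0.151. Also higher were GDF3, of the core and NODAL target lists, at 73.3 against 0.537, and SPP1, of no list, at 153 against 4.51. Primed markers were lower, with ZIC2 at 2.04 against 29.4 and THY1 at 1.63 against 30.3. Also lower were SFRP1 at 8.74 against 126 and FEZF1 at 0.0206 against 13.2, which are in no list. All 19 tested naive genes were higher, with a median of 3.46 (percentile 100), and 18 of 23 primed genes were lower (median -1.57, percentile 0). NODAL targets were at 1.71 and p53 targets at 1.08, both at percentile 100, and histones at -0.86 (percentile 0). Genes of other cell types were higher too: trophoblast genes at 1.70 (percentile 99.99, 7 of 7 higher) and fibroblast and feeder genes at 0.66 (percentile 98.7, 8 of 12 higher). At least 2-fold apart were 1215 genes higher and 434 lower, or 810 and 727 once the pair's median of 0.23 was removed. The rule also named short RNAs listed at 0 in 1 library, such as SNORA71D (645 RPKM in 5iLA). It also named NLRP7, SFRP1 and FEZF1, and the other protein-coding genes here were named after their values were seen.

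Across 10882 genes measured in both tables, the t2iGo minus primed change in H1 control cells and the 5iLA minus primed change in H7 had a Pearson r of 0.382 and a Spearman rho of 0.359. Of 971 genes that rose in H1, 78.4% were higher in H7 5iLA, where 66.0% of all genes were higher. Of 6726 that fell, 41.5% were lower. Relative to the median of each comparison the shares were 68.4% and 58.1%.

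Whether an shRNA acts differently in naive and primed cultures was tested with the difference of its effects. By limma 27 genes passed for pCCNE1 (13 higher, 14 lower in naive) and 19 for uCCNE1 (6 and 13), of which 12 and 14 were small non-coding RNAs. For CCNE1 itself the difference was -0.56 ± 0.44 for pCCNE1 and -0.26 ± 0.44 for uCCNE1 (limma, adjusted p = 0.796 and 0.983). The neural gene LHX5 differed by 2.85 for pCCNE1 and 3.04 for uCCNE1 (limma, adjusted p = 6.59e-04 and 4.83e-04), but it was below 0.1 RPKM in all 6 naive libraries and could not fall there, so this restates the primed pairs (-2.87 and -3.03). The primed side of each difference rests on 1 pair of libraries, and naive is the label of the cultures: it pools 5iLA with t2iGo, whose control library held DPPA5 at 0.138 RPKM against 273 in 5iLA. Without 1 naive library, an alternative chosen after seeing the data, 11 to 255 genes passed for pCCNE1 and 9 to 199 for uCCNE1. The counts of 179 or more came without the pCCNE1 library of either naive culture, where limma gave each gene the variance of the trend alone, and without a control or uCCNE1 library at most 18 passed. The LHX5 call ended without the 5iLA control (limma, adjusted p = 0.0998 for pCCNE1 and 0.0763 for uCCNE1) and without the t2iGo control (0.0657 and 0.0622).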

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

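All list tests on the difference between naive and primed effects, the leaving out of naive libraries or of an shRNA from it, and all tests of explanations below were chosen only after the result was seen. For the GC and length trend of the stress genes, only the expected outcome was set before that test. The lists and genes of the next 3 paragraphs were picked out because the effect of an shRNA in the cultures labelled naive differed from its effect in primed cells by a test of that difference. Their values are log2 differences, naive minus primed. The primed side is 1 pair of libraries, and the naive side pools 5iLA with t2iGo, which held few naive markers. Against their own controls, 5iLA and t2iGo had list medians of opposite sign after uCCNE1 for DNA replication (-0.58 and 0.04), trophoblast (0.53 and -0.09) and WNT genes (0.14 and -0.20), and after pCCNE1 for neuroectoderm genes (-0.02 and 0.09), with no test within a culture. The 3 patterns weighed after that were chosen once their values were seen. Of their lists, the stress genes (limma camera, adjusted p = 0.0556 for pCCNE1 and 0.504 for uCCNE1) and the NODAL targets (0.103 and 0.504) were not called for naive minus primed.

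For pCCNE1 shRNA, cholesterol synthesis genes differed most by p, with a list median of -0.91 (limma camera, adjusted p = 2.63e-07). Fibroblast and feeder genes were at 0.82 (7.75e-07), endoderm genes at 0.99 (6.40e-06), G2 and mitosis genes at -0.59 (0.00496) and trophoblast genes at 0.78 (0.00744) by the same limma camera test with adjusted p in brackets. Neuroectoderm genes were at 0.17 (0.0268), core pluripotency genes at -0.52 (0.0308) and p53 targets at 0.16 (0.0474) by limma camera, and these 3 calls were lost under quantile normalization and median-ratio scaling. The neuroectoderm and p53 calls were also lost with the GC and length trend removed, and the core and p53 calls without a filter. The trophoblast call was lost under median-ratio scaling and without a filter. Leaving out 1 naive library in turn ended the core call without either uCCNE1 library (limma camera, adjusted p = 0.0521 each), the t2iGo control (0.377) or the t2iGo pCCNE1 library (0.0861), and it was 0.0521 without all uCCNE1 libraries. The neuroectoderm call ended without the t2iGo control or pCCNE1 library (limma camera, adjusted p = 0.125 and 0.204), and the p53 call without these (0.378 and 0.0591) or the 5iLA pCCNE1 library (0.228). The core median stayed at -0.52 without uCCNE1 libraries, and was -0.40 without the t2iGo control and -0.38 without the t2iGo pCCNE1 library. The p53 median was -0.14 without the t2iGo control. The G2 and mitosis call ended without the t2iGo pCCNE1 library and the trophoblast call without the 5iLA control (limma camera, adjusted p = 0.0591 and 0.0503). With an estimated correlation none of the 8 lists passed (adjusted p = 0.759 to 0.996 with an estimated correlation).

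For uCCNE1 shRNA, neuroectoderm genes were at 0.78 (limma camera, adjusted p = 2.80e-07), fibroblast genes at 0.60 (3.55e-07), MYC and ribosome biogenesis genes at -0.63 (5.40e-06) and endoderm genes at 0.66 (4.35e-05). Against their own controls, the neuroectoderm medians were -0.63 in primed H1 (9 of 9 below 0), 0 in 5iLA (4 above, 3 below) and 0.21 in t2iGo (9 above). That difference rests largely on the primed pair, and its members include LHX5, which had no room to fall in the naive cultures. Histone genes were at -1.20 (limma camera, adjusted p = 3.64e-08), but primed H1 held almost none of their RNA (0.00581% to 0.0114% of summed RPKM, HIST1H4C at 0.950 RPKM with control), so a fall there shows little on the log2(RPKM + 1) scale and the difference does not compare the responses. Core pluripotency genes were at -0.59 (4.75e-04), DNA replication genes at -0.40 (0.00152), cholesterol synthesis genes at -0.47 (0.00365), trophoblast genes at 0.55 (0.0055) and WNT targets at 0.23 (0.0293) by limma camera with adjusted p in brackets. The calls of core, DNA replication and cholesterol genes were lost under quantile normalization, and that of WNT targets under both scalings and with the GC and length trend removed. Without a filter the endoderm, trophoblast and WNT calls were lost. Leaving out 1 naive library in turn ended the trophoblast and WNT calls without the 5iLA control (limma camera, adjusted p = 0.233 and 0.784) or the 5iLA uCCNE1 library (0.174 each), and the DNA replication call without the latter (0.0769). The WNT call also ended without either pCCNE1 library or without all of them (limma camera, adjusted p = 0.0616 each). None of the 10 lists passed with an estimated correlation (adjusted p = 0.634 to 0.873 with an estimated correlation).

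Among single genes, LHX5, a neural transcription factor, differed by 2.85 for pCCNE1 and 3.04 for uCCNE1 (limma, adjusted p = 6.59e-04 and 4.83e-04), being at 9.48 RPKM in the primed control and at 0.430 and 0.287 with the shRNAs. It was listed at 0 in 5iLA and at most 0.0504 RPKM in t2iGo, so it had no room to fall there and the difference restates the primed pairs (-2.87 and -3.03). That call ended without the 5iLA control (limma, adjusted p = 0.0998 and 0.0763) and without the t2iGo control (0.0657 and 0.0622). The other genes named by the rule were short or antisense RNAs with uncertain values and many entries listed at 0, so their fitted differences are no measure of size. Among all calls, 12 of 27 for pCCNE1 and 3 of 19 for uCCNE1 were protein-coding entries, LHX5 included. CYP26A1, named after its values were seen, was at 2.81 for pCCNE1 and 3.85 for uCCNE1 (limma, adjusted p = 0.0298 and 0.00426). PCNA-AS1 was at 5.02 for both shRNAs and SNORA42 at 3.85 for both, since among the 9 shRNA libraries both genes were above 0 in the primed control alone. SNORA72 was at -3.96, SNORA45 at -8.98 and SNORA6 at -8.16 for pCCNE1. SCARNA15 was at -3.46, MIR671 at -4.28 and MIR1282 at -10.17 for uCCNE1, with MIR1282 at 1153 RPKM in the primed uCCNE1 library and listed at 0 in the other shRNA libraries. The MIR671 call ended without the 5iLA control (limma, adjusted p = 0.0512).

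Small and histone RNAs were far higher in t2iGo than in primed H1. If the kind of library or its run were the cause, primed cells of another run would hold these RNAs. The histone list in untreated primed H7 lay a median of 5.21 above the primed H1 control (16 genes), across 2 tables treated as normalised separately. A lack of these RNAs in primed cells as such would put primed H7 well below its 5iLA partner, and the histone median of 5iLA minus primed H7 was -0.81 over these 16 genes (-0.86 over the 15 tested). The cell line differs between these libraries too, so that explanation stays open. A separate preparation of the primed H1 libraries may account for this pattern, and whether it also moved other genes compared between t2iGo and primed H1 was not tested. MFGE8, RARRES2, GPR176, NNAT, MIF and TCF7L1, named as falls, were also lower in untreated primed H7 than in the primed H1 control. The cell line and the table differ there too.

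The stress and unfolded protein response list was lower after both shRNAs. A deviant control library of 1 culture would lower the list in that culture alone, and it lay in the lowest 5% of random lists for both shRNAs in 2 of 3 cultures. Both shRNAs of a culture share 1 control library, so deviant controls in primed H1 and in 5iLA H7 would give the same pattern. The random lists also ignore the correlation between list members (estimated at 0.40), so the control libraries stay open as a cause. A bias of GC content and length could account for part of the fall. After the trend was removed 68.4% of the median was left (95% interval over genes 48.4% to 111%), so this stays open. A response to loss of cyclin E1 itself is a hypothesis that the shared control libraries keep untested.

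NANOG, POU5F1 and NODAL targets were mostly lower after pCCNE1 shRNA in t2iGo, with 11 of 16 genes lower relative to primed H1. Counting error at the low depth of that library is argued against, since the ratio of estimated reads to control had an upper bound of 0.467, which covers counting error only. Fewer pluripotent cells would lower the other core genes with POU5F1: their median change was 25.4% of that of POU5F1 (95% interval 7.53% to 57.3%), and the endoderm list was higher, so this may still contribute. Removing the GC and length trend left 110% of the median (interval -208% to 133%), too wide to decide. A response to the knockdown itself was not tested and stays open.

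With 10 splits of 6 libraries no share under 0.05 is possible, the smallest being 0.1. For pCCNE1 against control the real split gave 0 genes by limma and the highest other 7. For uCCNE1 against control and for pCCNE1 against uCCNE1 the real split gave 0 and the highest other 2. With a real count of 0 every split gives as many by construction, so these counts say nothing about chance. For t2iGo against primed 1 split, the real one, gave as many as its 8695 genes, and the highest other gave 0. Every other split mixes t2iGo with primed libraries and puts the gap between them into the residual, so its calls were bound to be few. This count cannot tell culture from preparation or run.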

How the results depend on the processing

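The restriction to protein-coding entries, the removal of the GC and length trend, the list tests on the naive minus primed difference, the leaving out of libraries from it and the estimated correlation under other scalings were chosen only after the result was seen. Depth limits low genes: a single read on 2 kb stood for up to 0.0780 RPKM. The cause was not tested for any change below except where given. Leaving out a naive culture left the naive minus primed difference 0 residual degrees of freedom and gave no test.

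Counts of changed genes by limma, 0 for pCCNE1 and for uCCNE1 against control, became 1 each without a filter, 4 and 1 with protein-coding entries, and for uCCNE1 38 with the 6 libraries compared and 1 with the GC trend removed. Without 1 culture they ran from 0 to 94 and from 0 to 123. For pCCNE1 against uCCNE1 the count of 0 became 1 with protein-coding entries and ran from 0 to 40 without 1 culture. The count for t2iGo against primed ran from 7521 to 8155 without 1 shRNA. For the naive minus primed difference, 27 genes for pCCNE1 became 11 (quantile), 9 (median-ratio), 15 (no variance trend), 43 (protein-coding) and 80 (GC trend removed), and 19 for uCCNE1 became 9 (no filter), 11 (quantile), 12 (median-ratio), 29 (protein-coding) and 53 (GC trend removed). Without 1 naive library, which leaves 1 residual degree of freedom, they ran from 11 to 255 and from 9 to 199, and without the other shRNA they were 13 and 198. The counts of 179 or more, all without a pCCNE1 library, came from fits in which limma estimated an infinite prior and gave each gene the variance of the trend alone.

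Counts of called lists were 6 for pCCNE1, with 2 at a pseudocount of 0.1, 1 each under quantile, median-ratio and no block, and 2 to 9 without 1 culture. The 5 of uCCNE1 became 3 (quantile), 2 (median-ratio) and 3 (no block), and 5 to 9 without 1 culture. The 5 of pCCNE1 against uCCNE1 became 3 (pseudocount 0.1), 3 (median-ratio) and 9 (GC trend removed), and 5 to 7 without 1 culture. The 8 of t2iGo against primed became 13 without a filter and 8 to 10 without 1 shRNA. For the pCCNE1 difference, with 8 lists as reported, 5 were called without a filter and 5 under median-ratio scaling, and 4 to 13 without 1 naive library and 8 to 14 for uCCNE1 (10 as reported). An estimated correlation gave 0 in every comparison, including both differences and, for t2iGo against primed, both other scalings, and fry called 0, 0, 0 and 18 lists. Fry, which does not compare a list with other genes, gave a direction opposite to that of camera for primed genes after pCCNE1 (list median 0.0382), and in t2iGo against primed for naive genes (0.16) and G1/S genes (-0.28).

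CCNE1 in t2iGo against primed (-0.48, adjusted p = 0.0438 by limma) was -0.48 without a filter (0.0583) and without the block (0.207), 0.34 under quantile (0.0688), 0.37 under median-ratio (0.0492), -0.0731 with the GC trend removed (0.749) and -0.58 to -0.28 without 1 shRNA. Without 1 culture CCNE1 was at -0.73 to -0.43 (pCCNE1), -1.01 to -0.74 (uCCNE1) and 0.27 to 0.58 (difference). Without 1 culture the trophoblast median for uCCNE1 ran from -0.10 to 0.28 and CCNE2 in the direct comparison from -0.44 to 0.00568, and both turned sign without the 5iLA libraries.

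With a pseudocount of 0.1, genes at least 2-fold apart numbered 882, 1816 and 1305 for pCCNE1 in primed, 5iLA and t2iGo (549, 700 and 419 as reported) and 780, 1740 and 406 for uCCNE1 (417, 662 and 123). For uCCNE1 they were 275 in primed under median-ratio, and 312 (quantile) and 401 (median-ratio) in 5iLA. The correlation of H1 and H7 changes was 0.338 without a filter, 0.347 under quantile and 0.358 under median-ratio, and that of both shRNAs ran from 0.481 to 0.657 without 1 culture. Among tested single genes and lists, 162 kept direction and side of the threshold without a filter and 11 lost a call, 154 and 19 under median-ratio, 153 and 20 under quantile, 164 and 9 at a pseudocount of 0.1. Of 189 values with no test, 4, 26 and 59 moved by more than the spread under the last 3 settings, in that order.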

Other observations

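The genes in this part were picked, and their tests chosen, only after the result was seen, except for the test of the interferon list. FOXH1, a transcription factor that acts with SMAD2 downstream of NODAL, was among the 1717 of 12116 genes (14.2%) below control in all 6 libraries with a CCNE1 shRNA, or 860 (7.10%) relative to the median of each pair. Unchanged groups sharing the 3 control libraries gave 3.71% over 100 simulations. That share follows from the shared controls alone and holds no shift or GC trend of a whole library. The gap to it therefore does not show a shared response to the shRNAs. FOXH1 stood at 23.4 RPKM in the primed control and at 11.7 with uCCNE1 and 12.002 with pCCNE1, at 5.51, 2.63 and 2.67 in 5iLA H7, and at 3.43, 1.496 and 1.66 in t2iGo H1. The averages were -0.87 ± 0.16 for uCCNE1 and -0.82 ± 0.16 for pCCNE1 (limma, adjusted p = 0.226 and 0.196), so neither passed.

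The interferon-induced gene BST2 was at 60.7 RPKM with control, 10.5 with uCCNE1 and 39.0 with pCCNE1 shRNA in primed H1, and ISG15 at 10.2, 2.14 and 1.68. The interferon list as a whole was not called for either shRNA (limma camera, adjusted p = 0.501 for pCCNE1 and 0.784 for uCCNE1). Matrix genes went both ways between t2iGo and primed H1: COL3A1 rose by 5.73 ± 0.29 and LUM by 4.60 ± 0.31, while COL1A2 changed by -3.23 ± 0.30 and COL6A1 by -2.76 ± 0.30 (limma, adjusted p at most 6.62e-06).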
